A study of Ovis aries with 8 samples.

How the data were processed

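Total RNA of carotid arteries from 8 sheep fetuses was hybridised, with Cy3 as the only dye, to 8 ovine arrays of Agilent design 019921. The 4 hypoxia and 4 normoxia samples were grouped by the maternal treatment in the labels, with the replicate number from each title. The titles give 110 days of hypoxia, while the treatment protocol gives gestation days 30 to 135. Adult arteries named in the series design were not used here.

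The deposited scanner files hold spot intensity on a linear scale, which the authors obtained with Agilent Feature Extraction 9.5.3.1 under protocol GE1-v5_95_Feb07, per the file headers. The processed intensity was background-subtracted and detrended by that software, per the file headers, with no scaling between arrays, and the mean spot intensity and median local background intensity were uncorrected. The deposited flags mark spots well above background, saturated or outlying, per the file headers. The authors' series table holds a ratio, which from its values is the processed intensity over each array's 75th percentile on a linear scale. Its floor was 0.01, reached by 24.2% of probes on normoxia 2, 24.6% on hypoxia 4, 5.38% on normoxia 3 and 2.47% on hypoxia 3. The medians of its columns were 0.328, 0.132, 0.228, 0.137 for normoxia 1 to 4 and 0.326, 0.158, 0.308 and 0.141 for hypoxia 1 to 4. Each column, after log2, correlated across probes with the scanner values of its own array, with 0.995 on hypoxia 4 as the lowest value. How the authors chose this scale was not given in the sources used here.

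Each array held 15744 spots, of which 536 were controls and were left out, which left 15208 spots of 15008 probes. Spots marked as outliers were left out, and the 72 probes left with no value on at least 1 array were dropped from the main tests. Saturated spots were kept (1 probe each on hypoxia 1 and hypoxia 4). The log2 processed intensity minus each array's 75th percentile was averaged over the spots of a probe. A probe was kept where it was well above background on at least 4 of the 8 arrays, and the probe with the highest mean stood for its gene. The values of other kept probes of a named gene are given beside it. No named gene was below background on all arrays of a group.

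Gene names came from the name, accession or description in the files, matched to a list of RefSeq genes of assembly ARS-UI_Ramb_v3.0, which was used for names only. Of 563 probes with a RefSeq accession, 520 matched a gene symbol by it and 23 a locus number. A name was had for 1409 of 15008 probes, for 806 distinct genes, and 13599 probes had no name here and stayed in the tests as their own features. HSP70.1 is a name from the files with no match.

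Hypoxia was compared with normoxia by limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with data.table (version 1.17.8), with Benjamini-Hochberg adjustment over 10848 features and a threshold of 0.05. Log2 fold changes are hypoxia minus normoxia. A more lenient count took an unadjusted p under 0.05 and a fold of at least 1.5. Gene lists with at least 5 measured members were tested by limma's camera with a preset correlation of 0.01. Separation of the groups was tested by exact permutation over 35 splits. The tests, the alternatives, 24 gene lists and the rule for named genes were fixed before the data were examined. The lists were glycolysis and glucose uptake, other hypoxia-inducible factor targets, contractile smooth muscle, calcium handling and ion channels, vasoactive receptors and contraction signalling, extracellular matrix, growth factors, oxidative phosphorylation, cell cycle, ribosomal proteins, interferon response, inflammatory mediators, immediate early genes, heat shock and unfolded protein response, antioxidant and nitric oxide, and markers of endothelium, adventitial fibroblasts, leukocytes, erythroid cells, adipocytes, nerve, skeletal muscle, thyroid and thymus, and fetal sex. Of these, 14 were tested, 6 had 1 to 4 measured members and 4 had none.

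The named genes were, in each direction, those with an adjusted p under 0.05 and no overlap between groups, filled up to 5 with the smallest p among named genes with no overlap. They also included the 2 members of each list with the smallest p, and VEGFA, SLC2A1, HIF1A, EPAS1, ACTA2, MYH11 and NOS3 where measured. Other list members are given as examples only.

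The groups share replicate numbers. Over genes, the correlation of the deviations of same-numbered arrays from their group means was 0.819, 0.724, 0.583 and 0.433 for numbers 1 to 4, so the numbers were taken to pair the arrays. This pairing comes from the values, since the labels do not say what a number shares, and normoxia 2 correlated better with hypoxia 4 (0.801), an array of the same slide. The file headers place normoxia 1 and hypoxia 1, 2 and 3 on slide 1, normoxia 2 and hypoxia 4 on slide 2, and normoxia 3 and 4 on slide 3, with scans coinciding with slides.

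The procedure was tested on simulated data of 10848 genes for hypoxia against normoxia, with 50 genes changed at each fold. Without a block it called 0% at a fold of 2, 30% at 4, 42% at 8 and 66% at 16, with 0 false calls. With the replicate block it called 8%, 60%, 62% and 84%, with 4 false calls. Each simulated gene held the part that same-numbered real arrays shared, so the higher share with the block follows from how the data were made. It does not bear on whether the arrays are paired. In 40 simulated data sets of 10848 genes, camera called a list where none was shifted in 3 data sets and called the shifted list in 40. The shifted list was ribosomal proteins, raised by a fold of 2 in every member. The simulated noise was independent between genes, while the estimated correlation within the real lists reached 0.872 for skeletal muscle markers. The simulation therefore does not measure how often camera at the preset correlation falsely calls a list, or finds a changed one, in these data.

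Alternatives were normexp background correction (offset 50), quantile, median and cyclic loess scaling, no probe filter, a filter on all 8 arrays, the mean of a gene's probes, a trended robust variance, array weights, the replicate block, slide as a block, the series table, each array left out in turn, a fold of 2, an estimated correlation and fry. Others, chosen after seeing the data, left out replicates 1 and 3 of both groups or joined the replicate block with the all-array filter, quantile normalization or normexp. An estimated correlation was also joined, after seeing the data, to each setting in which a list passed.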

Results

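Gene expression was measured in carotid arteries of 8 sheep fetuses at gestation day 140, with 1 single-colour Agilent ovine array per fetus. In the hypoxia group, 4 fetuses came from ewes kept at an altitude of 3801 m from gestation day 30 until day 135. In the normoxia group, 4 fetuses came from ewes kept at 300 m. The comparison asked how long-term maternal hypoxia altered gene expression in the wall of the fetal carotid artery. The labels tell the fetuses apart by a number in the title only, so p-values measure the spread between these samples. The 75th percentile of the processed signal ranged from 97.9 on hypoxia 1 to 1387 on normoxia 3. The percent of probes well above background ranged from 59.6 on normoxia 4 to 94.8 on hypoxia 3. The number of arrays limits the precision of every value.

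Arrays with the same replicate number in the 2 groups resembled each other more than arrays of the same group did. The mean Pearson correlation across genes was 0.940 for arrays sharing a number, 0.874 for arrays of the same group and 0.883 for arrays of different groups, where genes are not independent replicates. The mean distance between groups minus that within groups was -0.00983, with an exact permutation p of 0.6 over the 35 splits of the 8 arrays into 4 and 4, one-sided. The largest separation, 0.0724, came from the split with replicates 1 and 3 of both groups on one side and replicates 2 and 4 on the other. The first principal component held 69.6% of the variance and followed the same division. Genes restricted to other organs, listed after this component was seen, differed in brightness along it. Their median log2 signal was -2.06 on normoxia 1 and -2.04 on hypoxia 1, against -6.35 on normoxia 2 and -6.16 on hypoxia 4. Only 36.4% of these genes were well above background on normoxia 2, hypoxia 2 and hypoxia 4, so the medians there lay near the floor of the arrays. The separation changed sign to 0.00313 over the 1000 genes of largest variance (exact permutation p = 0.314) and to 0.00419 without hypoxia 1.

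**Figure D1:**
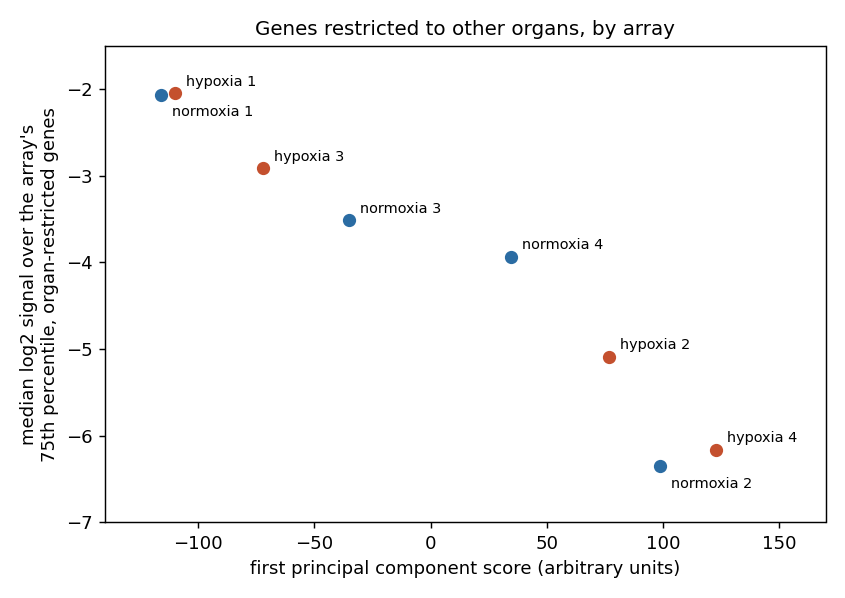
Median log2 signal, relative to each array's 75th percentile, of 22 genes restricted to other organs (y axis) against the array's score on the first principal component (x axis, arbitrary units), with blue points for normoxia and orange points for hypoxia. The median ran from -2.04 on hypoxia 1 to -6.35 on normoxia 2, and both groups spread along the whole axis.

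Among genes with a name whose 4 hypoxia values all lay above the 4 normoxia values, TGFB3, a ligand of the TGF-beta family, had the smallest p. Its log2 level was 0.64 ± 0.37 (SD, n = 4) in hypoxia and -0.71 ± 0.68 (SD, n = 4) in normoxia, relative to each array's 75th percentile. HSP70.1, a heat shock protein under the name the array gives it, had a log2 fold change of 1.11 (SE 0.41), ETS2, a transcription factor, 0.76 (SE 0.30), TRPC4AP 0.58 (SE 0.25) and YWHAE, a 14-3-3 protein, 0.55 (SE 0.27). In the other direction 3 named genes had no overlap between groups. ALOX5AP, which activates 5-lipoxygenase in leukotriene synthesis and was well above background on 4 normoxia and 3 hypoxia arrays, was at -2.74 ± 0.21 (SD, n = 4) in hypoxia and -1.58 ± 0.38 (SD, n = 4) in normoxia, FCER1G, an Fc receptor subunit of leukocytes, had a log2 fold change of -0.72 (SE 0.27), and ATP1B1, a sodium pump subunit, -0.71 (SE 0.27).

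None of these genes passed the test. With limma, 0 of 10848 features had a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.998. TGFB3 (probe A_70_P031232) had a log2 fold change of 1.35 and an unadjusted p of 0.00855, and ALOX5AP (probe A_70_P016781) had -1.15 and 0.00290. A second probe gave 1.43 for TGFB3, 0.99 for HSP70.1, 0.54 for YWHAE, -1.29 for ALOX5AP, -0.36 for FCER1G and -0.50 for ATP1B1. With slide as a block the log2 fold change was 1.20 for TGFB3 and -0.80 for ALOX5AP. Within slide 1 it was 1.04 and -0.72, and within slide 2 it was 1.44 and -0.91, where the absence of overlap fixes the sign. Each within-slide value rests on 1 normoxia array, and within slide 2 on 1 hypoxia array too. Slide 3 held normoxia arrays only, so it adds nothing to the log2 fold change with slide as a block. That value is a weighted mean of the values within slides 1 and 2, not a separate check. The same holds for the slide values of all genes and lists given below. Slide values for the other genes with no overlap were 0.98 for HSP70.1, 0.78 for ETS2, 0.56 for TRPC4AP, 0.64 for YWHAE, -0.77 for FCER1G and -0.35 for ATP1B1.

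The unadjusted count was below the number that chance gives for unpaired arrays. At an unadjusted p under 0.05 there were 396 features, against 542 expected by chance if no arrays were paired. Of these, 382 had a fold of at least 1.5, 312 higher and 70 lower in hypoxia. Where same-numbered arrays are alike, an unpaired test gives fewer than 542 by chance, so the 396 cannot be read as below chance. The other splits that part all 4 pairs gave 33 to 142 features with that fold, too few splits for a test. Only 608 of the 10848 features had a gene name, and the 382 included 11 named genes higher and 3 lower. The groups did not overlap in 290 features, 2.67% of those tested, against 2.86% by chance for unpaired arrays. Among probes with no gene name and no overlap between groups, those with the smallest p in each direction were as follows. A_70_P028616 and A_70_P031411 had log2 fold changes of 2.26 and 2.10, and A_70_P002261 and A_70_P018256 had -0.96 and -1.69. With the replicate number as a block 0 features passed by limma, the smallest adjusted p was 0.313, 1300 features had an unadjusted p under 0.05, and 1112 also had the fold (879 higher, 233 lower), 377 of them among the 382. The count of 382 became 243 without normoxia 2, 594 without normoxia 3, 177 without normoxia 4, 251 without hypoxia 2 and 186 without hypoxia 3. With normexp background correction it became 23 (8 higher, 15 lower), with median scaling 137, with cyclic loess 452 (318 higher, 134 lower), with array weights 1120 and with slide as a block 192. The median log2 fold change of all features was -0.02, and it was -0.31 with normexp, -0.20 with median scaling and -0.10 with slide as a block. Median scaling moved every feature by the same -0.18, so a change of sign under it restates that shift and says nothing about the genes of a list. With normexp and with slide as a block the median also moved, but features did not all move alike. AGTR1, at -0.36, rose to 0.11 with normexp and to 0.72 with slide as a block. The mean of endothelial markers with normexp, -0.30, lay at the median of all features. Counts of higher or lower members under normexp, median scaling and slide as a block, given below, are affected by these moves of the median too.

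**Figure D2:**
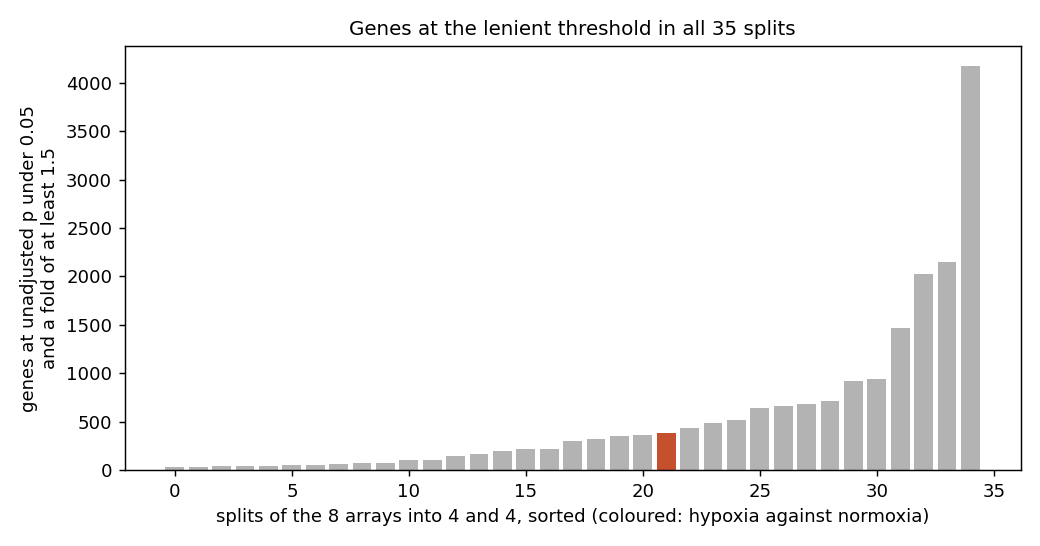
Number of features at an unadjusted p under 0.05 and a fold of at least 1.5 (y axis) in each of the 35 splits of the 8 arrays into 4 and 4 (x axis, sorted by that number), with the split of hypoxia against normoxia in orange. The hypoxia split gave 382 features, the highest of the other splits gave 4170, and the highest of the other splits that part all 4 pairs gave 142.

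Genes of the response to low oxygen were at mixed values. Of 6 measured members of the list of other hypoxia-inducible factor targets, 4 were higher and 2 lower, but 1 was higher with normexp and 3 with median scaling and cyclic loess, 0 passed over all genes tested, and 0 passed adjusted over the list alone. CITED2, a coactivator induced by hypoxia, had a log2 fold change of 0.97 (SE 0.40), higher in 4 of 4 pairs. VEGFA, the endothelial growth factor, had 0.88 (SE 0.62). HIF1A had 0.73 (SE 1.30) and was well above background on 2 normoxia and 3 hypoxia arrays. EPAS1 had 0.01 (SE 0.96), was well above background on 3 arrays of each group, and its other 3 probes gave -0.03 to 1.0. With normexp, VEGFA, HIF1A and EPAS1 were at -0.33, -0.66 and -0.63. With slide as a block the values were 1.06 for CITED2, 0.35 for VEGFA, 0.10 for HIF1A and -0.46 for EPAS1. Within slides 1 and 2 the values were 1.62 and 0.23 for CITED2 and 0.26 and 0.49 for VEGFA, but reversed between the slides for the 2 transcription factors, with -1.06 and 1.83 for HIF1A and -0.85 and 0.13 for EPAS1. A second probe gave 0.83 for CITED2 and 0.55 for VEGFA. The mean over the list was 0.30 (limma camera adjusted p = 0.319), -0.02 with slide as a block, -0.28 within slide 1 and 0.36 within slide 2.

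Of 8 measured members of glycolysis and glucose uptake, 6 were higher and 2 lower, but 4 and 4 with normexp and under the uniform shift of median scaling, and 0 passed, also 0 adjusted over the list alone. PFKL, a phosphofructokinase subunit, had a log2 fold change of 0.61 (SE 0.37), and HK1, a hexokinase well above background on 2 normoxia and 4 hypoxia arrays, had 0.99 (SE 0.71). SLC2A1, the glucose transporter also called GLUT1, had -0.55 (SE 0.64), while its other probe gave 0.11. Both HK1 and SLC2A1 reversed between slides 1 and 2, with -0.51 and 2.20 for HK1 and -1.85 and 0.53 for SLC2A1. Leaving out 1 array brought SLC2A1 closest to 0 at -0.10 without hypoxia 2. With normexp HK1 was at -0.54. The mean over the list was 0.14 (camera adjusted p = 0.316), -0.01 with slide as a block, -0.48 within slide 1 and 0.70 within slide 2. Without hypoxia 3 the list passed at the preset correlation, at a mean of 0.43 (camera adjusted p = 0.0383), but not at the estimated one of 0.136 (adjusted p = 0.723), and without normoxia 2 its mean was -0.03. Both measured subunits of the ATP synthase, ATP5MC1 and ATP5MC2, the only members of oxidative phosphorylation with a value, were lower in 4 of 4 pairs, at -0.45 and -0.56. Their count adjusted over the list alone was 0 by limma and 2 with the replicate block, each at an adjusted p of 0.0498. The other 3 probes of ATP5MC1 gave -0.35 to -0.06, and within slides 1 and 2 the values were -0.24 and 0.03 for ATP5MC1 and -0.53 and -0.37 for ATP5MC2. The mean of these 2 genes was -0.51, -0.30 with slide as a block, -0.39 within slide 1 and -0.17 within slide 2.

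Matrix genes ran from -0.60 to 1.80. Of 8 measured members of the extracellular matrix list, 4 were higher and 4 lower, with 3 higher under normexp, 5 under quantile normalization and 6 under cyclic loess. COL3A1, a fibrillar collagen chain of the vessel wall, had a log2 fold change of 1.80 (SE 0.81) and was higher in 4 of 4 pairs, while its other 2 probes gave 0.53 and 0.54. Its values were 2.24 with slide as a block, 2.65 within slide 1 and 1.61 within slide 2. COL1A1, well above background on 3 arrays of each group, had 0.96 (SE 0.53) and changed sign to -0.14 with normexp. Adjusted over the list alone, 0 genes passed by limma and 1 passed with the replicate block, COL3A1 at an adjusted p of 0.00656. The mean over the list was 0.42 (camera adjusted p = 0.316), 0.51 with slide as a block, 0.77 within slide 1 and 0.12 within slide 2.

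In the list of growth factors, TGF-beta, Notch and IGF signalling, 12 of 24 measured genes were higher and 12 lower (8 higher with normexp, 9 with median scaling), and 0 passed adjusted over the list alone. Besides TGFB3, IGFBP3, which binds insulin-like growth factors, was at 3.12 ± 0.40 (SD, n = 4) in hypoxia and 1.79 ± 0.79 (SD, n = 4) in normoxia. Its log2 fold change was 1.33, with 1.36 from a second probe, and it was 0.75 with slide as a block, 0.06 within slide 1 and 1.80 within slide 2. IGF2R, the receptor that clears IGF2, was chosen after its values were seen, was well above background on 2 normoxia and 4 hypoxia arrays, and had 2.48 (SE 0.95), while its other 2 probes gave -0.27 and 1.84. The mean over the list was 0.16 and the median 0.01 (camera adjusted p = 0.316), -0.21 with slide as a block, -0.35 within slide 1 and -0.02 within slide 2.

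**Figure D3:**
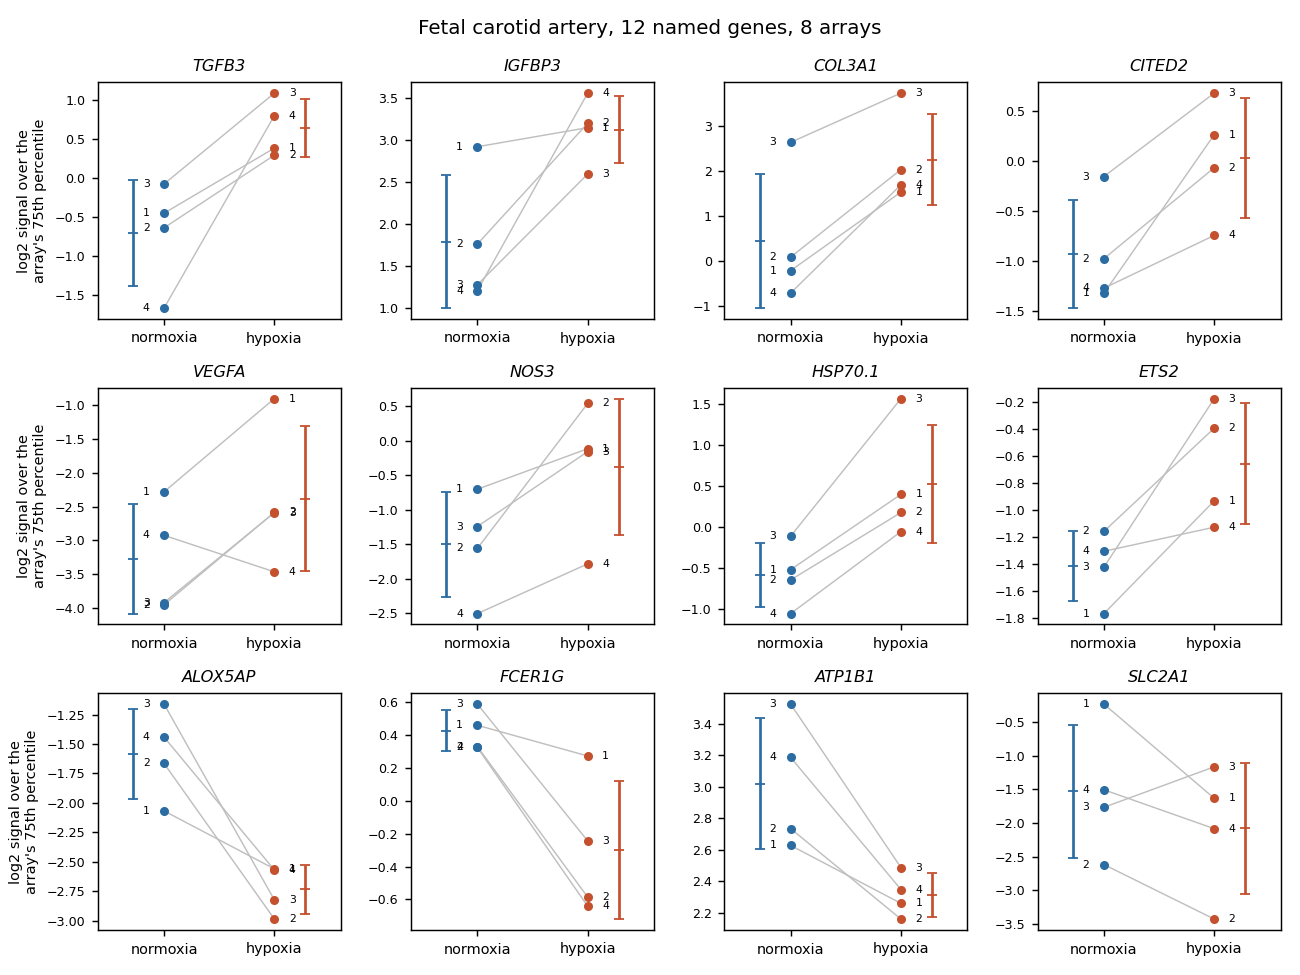
Log2 signal relative to each array's 75th percentile (y axis) of 12 named genes in normoxia (blue) and hypoxia (orange), with 1 point per array numbered by replicate, grey lines joining arrays with the same number, and bars for the mean and SD of 4 arrays. TGFB3, HSP70.1 and ETS2 had every hypoxia value above every normoxia value, and ALOX5AP, FCER1G and ATP1B1 had every hypoxia value below, yet 0 genes passed the adjusted threshold.

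Contractile genes were bright on every array and did not separate the groups. CNN1, the calponin of smooth muscle, had a log2 level of 7.28 ± 1.58 (SD, n = 4) in hypoxia and 7.90 ± 0.69 (SD, n = 4) in normoxia, and MYLK, myosin light chain kinase, had 5.39 ± 1.03 and 5.99 ± 1.02 (SD, n = 4). All 3 measured members, with MYL6 at -0.37, had negative log2 fold changes under the 4 other scalings and background corrections, but MYLK changed sign to 0.11 with slide as a block. Within slides 1 and 2 the values were -0.40 and 0.87 for MYLK and -0.82 and 0.30 for CNN1, and MYLK was as near 0 as -0.09 without normoxia 4. CNN1 changed sign to 0.14 without hypoxia 1. By limma 0 members passed adjusted over the list alone, and the mean was -0.53, -0.10 with slide as a block, -0.39 within slide 1 and 0.34 within slide 2. ACTA2 and MYH11 were not analysed here. Among 8 vasoactive receptors and contraction signalling genes, 3 were higher and 5 lower. Under quantile, median and cyclic loess scaling 2 were higher, with normexp 1 and with slide as a block 4. GUCY1B1, a subunit of soluble guanylate cyclase, was at 0.48 (SE 0.51) and AGTR1, an angiotensin receptor, at -0.36 (SE 0.75). With slide as a block AGTR1 changed sign to 0.72, and it was at 0.56 within slide 1 and 0.97 within slide 2. A second probe of GUCY1B1 gave 0.84. The endothelin receptors EDNRA and EDNRB were at 0.02 and -0.09. The count adjusted over the list alone was 0, and the mean was -0.08 (camera adjusted p = 0.773), -0.20 with slide as a block, -0.28 within slide 1 and -0.09 within slide 2.

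Endothelial markers were higher in 4 of 5 measured genes, but in 3 under median scaling and cyclic loess and in 2 under normexp. NOS3, the endothelial nitric oxide synthase, had a log2 fold change of 1.12 (SE 0.57) and was higher in 4 of 4 pairs, at 0.39 with slide as a block, 0.79 within slide 1 and -0.22 within slide 2. TIE1, an endothelial receptor kinase well above background on 1 normoxia and 3 hypoxia arrays, had 2.14 (SE 1.09), with 2.42 from a second probe, and hypoxia 4 stood apart at a log2 level of -6.19. TIE1 reversed between slides 1 and 2, with 3.69 and -1.60. KDR was at 0.81 and FLT1 at -0.91. With 0 members passing adjusted over the list alone, the mean was 0.66 (camera adjusted p = 0.289), 0.12 with slide as a block, 0.52 within slide 1 and -0.48 within slide 2. With normexp the mean was -0.30, and without hypoxia 4 the list passed at a mean of 1.30 (camera adjusted p = 0.00519), but not at its estimated correlation of 0.372 (adjusted p = 0.487).

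Leukocyte markers were lower in 7 of 7 measured genes, and in 6 of 7 under quantile normalization and cyclic loess. FCER1G had a log2 fold change of -0.72, and CD3E, a T cell receptor component well above background on 4 normoxia and 2 hypoxia arrays, had -0.70 (SE 0.72) and was as near 0 as -0.13 without hypoxia 2. By limma 0 members passed adjusted over the list alone, and the mean was -0.39 (camera adjusted p = 0.289), -1.0 with slide as a block, -1.24 within slide 1 and -0.64 within slide 2. With slide as a block the list passed at the preset correlation of 0.01 (camera adjusted p = 0.0293), but not at the estimated correlation of 0.675 (adjusted p = 0.815). At the preset correlation it also passed without hypoxia 1, at a mean of -0.87 (camera adjusted p = 0.0439), and without hypoxia 3, at -0.78 (camera adjusted p = 0.0383), while the mean was 0.00315 without hypoxia 2 and 0.10 without hypoxia 4. At the estimated correlation it passed neither without hypoxia 1 (adjusted p = 0.718) nor without hypoxia 3 (adjusted p = 0.723).

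Adipocyte markers were lower in 6 of 6 measured genes, under each scaling too, with SCD, a fatty acid desaturase, at -1.10 (SE 1.72) and LEP, leptin, at -0.55 (SE 0.96), both well above background on 3 normoxia and 2 hypoxia arrays. The mean was -0.56 (camera adjusted p = 0.316), -1.35 with slide as a block, -1.20 within slide 1 and -1.58 within slide 2. The list passed with slide as a block at the preset correlation (camera adjusted p = 0.0293), but not at the estimated correlation of 0.476 (adjusted p = 0.815). Leaving out 1 array brought SCD as near 0 as -0.06 without hypoxia 4. SCD was at -0.81 on normoxia 1 and -1.06 on hypoxia 1 but at -6.04 on normoxia 2, -6.57 on hypoxia 2 and -7.19 on hypoxia 4. On these last arrays the median of organ-restricted genes was also low. The list turned to a mean of 0.28 without hypoxia 4. Skeletal muscle markers were higher in 1 and lower in 4 of 5 genes (lower in 5 with normexp), with the oxygen-binding protein gene MB at 0.59 against -0.30 from its other probe and MYH1, one of a family of near-identical myosins, at -1.17. Their mean was -0.45 (camera adjusted p = 0.516), -1.16 with slide as a block, -1.18 within slide 1 and -1.13 within slide 2, and 0.32 without hypoxia 4. MB was well above background on 2 normoxia and 4 hypoxia arrays, and MYH1 on 3 and 2. Among erythroid markers HBB, a globin with near-identical copies, was at 0.36 and AHSP, a haemoglobin chaperone well above background on 3 arrays of each group, at 0.16, and AHSP changed sign under normexp, quantile, median and cyclic loess scaling, with a mean of 0.26, -0.21 with slide as a block, -1.27 within slide 1 and 1.38 within slide 2. Other probes gave 0.41 for HBB and 0.09 for AHSP, and both reversed between slides 1 and 2, with -0.72 and 0.61 for HBB and -1.82 and 2.15 for AHSP. The nerve and Schwann cell marker GFAP, well above background on 2 normoxia and 4 hypoxia arrays, was at 0.75. It was 0.34 within slide 1 and changed sign to -0.47 with normexp, -0.01 with slide as a block and -0.53 within slide 2. Its second probe gave 0.83. GFAP passed adjusted over the list alone only with the replicate block, as its list's single measured member, at 0.0229. Adjusted over the list alone, 0 genes of the adipocyte, skeletal muscle and erythroid lists passed.

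Immediate early genes, which respond within minutes to stimuli, were higher in 8 of 8 measured genes. The count was 3 under normexp and 7 under median scaling, where the medians of all features were -0.31 and -0.20. With normexp the mean of the list was 0.09, above that median. JUND was at 0.81 (SE 0.58) and FOS at 0.57 (SE 0.36), with 0.98 from a second probe of FOS, 0.56 for JUN and 0.05 for ZFP36. Under quantile normalization and cyclic loess 8 of 8 were higher, and with slide as a block 4. With normexp FOS was at -0.28. The count adjusted over the list alone was 0, and the mean was 0.41 (camera adjusted p = 0.289), 0.13 with slide as a block, 0.30 within slide 1 and -0.12 within slide 2. The list passed with the mean of all kept probes, at 0.56 (camera adjusted p = 0.0210), with array weights, at 0.61 (adjusted p = 0.0359), and without hypoxia 4, at 0.64 (adjusted p = 0.0354). At the estimated correlation it passed in none of these 3 settings (adjusted p = 0.744, 0.717 and 0.487).

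Ribosomal protein genes were lower in 14 of 16 measured genes, but in 10 under quantile normalization and in 4 under cyclic loess, where the mean changed sign to 0.12. RPS26 was at -0.59 (SE 0.36), with -0.63 from a second probe, and RPL32 at 0.65 (SE 0.31), and probes of this family can bind transcripts of processed copies. The mean was -0.14 (camera adjusted p = 0.316), -0.25 with slide as a block, -0.28 within slide 1 and -0.21 within slide 2. The list passed with array weights at -0.28 (camera adjusted p = 0.0359) and without hypoxia 1 at -0.44 (camera adjusted p = 3.00e-04). At the estimated correlations of 0.682 and 0.522 it passed in neither setting (adjusted p = 0.787 and 0.718), and its mean was 0.09 without hypoxia 3. In cell cycle, PCNA, the DNA polymerase clamp, was at -0.28 against 0.08 from its other probe, and TYMS, thymidylate synthase, well above background on 4 normoxia and 3 hypoxia arrays, at 0.04 and negative under every other scaling, with a mean of -0.12, 0.12 with slide as a block, 0.15 within slide 1 and 0.09 within slide 2. Adjusted over the list alone, 0 genes of the ribosomal and cell cycle lists passed.

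In the list of heat shock, unfolded protein and glucocorticoid response, 4 of 7 genes were higher, with HSP90AA1, a chaperone, at 0.74 (SE 0.37) and DDIT3, a stress-induced transcription factor well above background on 3 normoxia and 2 hypoxia arrays, at -0.66 against 0.34 from its other probe. HSP70.1, at 1.11, was not counted in this list, since its name had no match. DDIT3 reversed between slides 1 and 2, with -1.91 and 0.10. The mean was 0.05, negative with normexp and median scaling, and the median 0.28 (camera adjusted p = 0.633), 0.28 with slide as a block, 0.27 within slide 1 and 0.31 within slide 2. Of 7 antioxidant and nitric oxide genes 6 were lower, with NOS2, the inducible nitric oxide synthase well above background on 2 arrays of each group, at -1.36 (SE 1.62) and TXN, thioredoxin, at -0.36 (SE 0.25). Their second probes gave -0.49 for NOS2 and -0.15 for TXN. That mean was -0.39 (camera adjusted p = 0.316), -0.68 with slide as a block, -0.65 within slide 1 and -0.71 within slide 2, and 0.03 without hypoxia 4. Of 11 inflammatory mediators 7 were lower, 8 with cyclic loess and with slide as a block, 9 with median scaling and 10 with normexp. The prostaglandin synthases PTGS1 and PTGS2 were at -0.49 and -0.31, the latter at -0.32 within slide 1 and 0.19 within slide 2. The mean of inflammatory mediators was -0.13 (camera adjusted p = 0.516), -0.46 with slide as a block, -0.54 within slide 1 and -0.35 within slide 2. Among interferon response genes, 3 of 4 were higher, but 2 with median scaling and 0 with normexp, and MX2 was at 0.43 and MX1 at -0.36, with a mean of 0.12, -0.05 with slide as a block, -0.57 within slide 1 and 0.74 within slide 2. Both reversed between slides 1 and 2, with -0.01 and 1.15 for MX2 and -1.32 and 0.61 for MX1. Adjusted over the list alone, 0 genes passed in each of these 4 lists.

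Of the 14 lists tested, 0 passed by camera with its preset correlation, and the 3 lists with the smallest adjusted p, immediate early genes, endothelial markers and leukocyte markers, shared 0.289. At an unadjusted p under 0.05 there was 1 list, immediate early genes. With an estimated correlation 0 lists passed, at a smallest adjusted p of 0.780, and with fry 0 passed, at 0.850. With the replicate block 0 passed, at 0.272. The count of 0 became 2 without hypoxia 1, 2 without hypoxia 3 and 2 without hypoxia 4 at the preset correlation, and stayed 0 without each of them at an estimated one. Calcium handling and ion channels, adventitial fibroblast markers, thyroid and thymus markers, and Y-linked genes and XIST had no measured member.

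**Figure D4:**
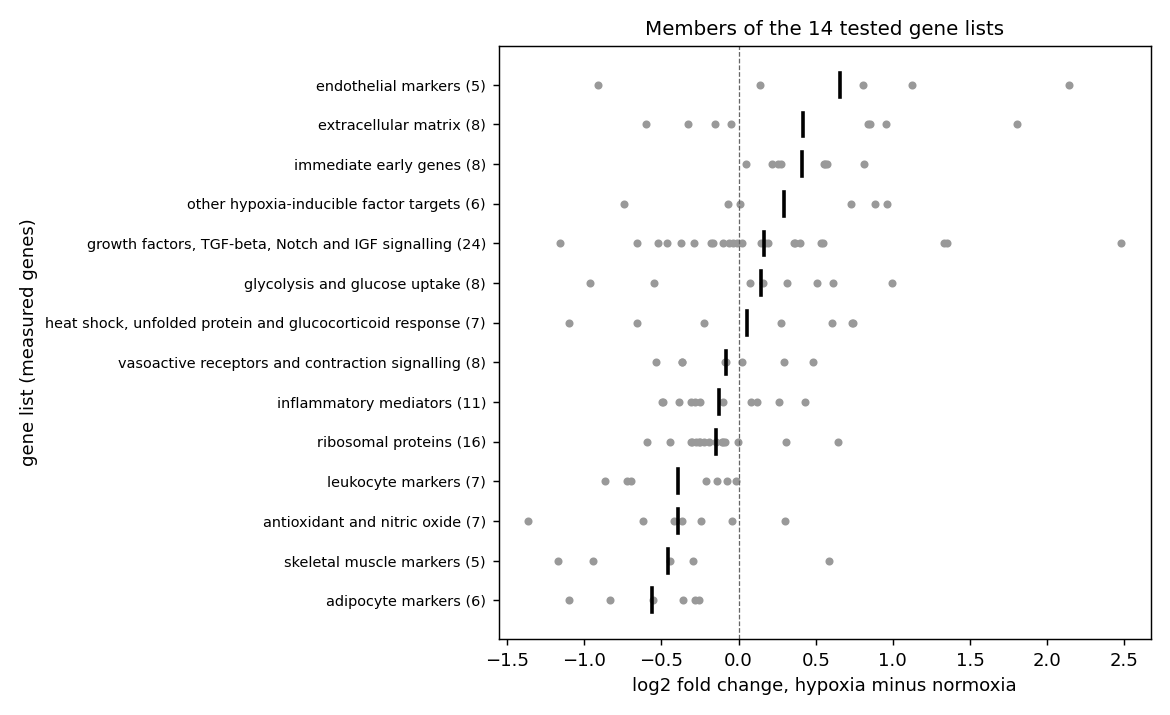
Log2 fold change of hypoxia minus normoxia (x axis) for each measured member (grey points) of the 14 tested gene lists (y axis, with the number of measured genes), with a black bar at the mean of each list. The means ran from -0.56 for adipocyte markers to 0.66 for endothelial markers, and 0 lists passed the test.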

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

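The tests of what the arrays with the same replicate number share and of the scaling between arrays were chosen after the result was seen. In 4 of 104 groups of 4 arrays, 1 array lay far from the others, and chance alone marks about 1 in 20 groups. MYLK, the smooth muscle myosin kinase, had a log2 level of 7.52 on normoxia 4, against 5.38 to 5.54 on the other normoxia arrays. FOS was at -2.58 on hypoxia 4, against -1.92 to -1.80 on the other hypoxia arrays. HSP90AA1 was at 1.56 on hypoxia 2, against 2.50 to 2.68. TIE1 was at -6.19 on hypoxia 4, against -1.71 to -1.25.

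Arrays with the same replicate number deviated together, and the first principal component set replicates 1 and 3 apart from 2 and 4. Arrays of numbers 2 to 4 lie on different slides, yet deviated together at a mean r of 0.580 (lower 95% limit 0.218, t over 3 pairs). This argued against slide as the whole source for these numbers. The mean r over the 4 pairs was 0.507 in the brighter features (lower 95% limit 0.264) and 0.539 in the dimmer ones, which argued against dim probes as the whole cause. In the brighter features r was 0.660, 0.304, 0.577 and 0.487 for numbers 1 to 4, so number 2 fell from 0.724. The same correlations had led the numbers to be paired. They depend on each other, since deviations within a group sum to 0, so the t limits do not measure their spread. For number 1, whose arrays share slide 1, slide stayed open: arrays on 1 slide correlated better than others by 0.00570 (exact permutation p = 0.348), and among same-slide arrays with different numbers normoxia 1 deviated with hypoxia 3 at r = 0.575 and with hypoxia 2 at r = -0.637, and normoxia 2 with hypoxia 4 at r = 0.801, above the 0.724 of number 2. Whole-array brightness stayed open at rho = 0.381 with the component (exact permutation p = 0.360). The r of -0.976 for genes restricted to other organs decided nothing, since their median lay near the floor on normoxia 2, hypoxia 2 and hypoxia 4. On each of these arrays 36.4% of them were well above background. LHB, the brightest there, was at 3.06, 2.74 and 2.78. A shared litter, day or other biological source of the numbers was not tested.

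More genes were higher than lower in hypoxia at the lenient threshold, 312 against 70. Among the calls in dimmer genes 92.5% were higher, and among those in brighter genes 69.9%, which left a part played by dim probes open, and with normexp, a background correction that moved the median of all features to -0.31, the share was 34.8% of only 23 calls. The excess was 276 against 94 under quantile, 115 against 22 under median and 318 against 134 under cyclic loess scaling, which argued against scaling between arrays. But the lowest share, 70.4%, had a 95% exact binomial interval from 65.9 to 74.5 and did not settle it. That interval takes the calls as independent, which features on an array are not, so it does not measure the spread of the share. An excess as large as the real 242 came in 12 of the 35 splits, with 2632 as the highest of the others, so chance cannot be excluded over all splits, while in the other splits that part all 4 pairs it was 8 to 47, and these 8 splits are too few for a share under 0.05. Hypoxia itself stays open as an explanation.

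The replicate block raised the lenient count from 382 to 1112. Genes called from pairs 2 to 4 had the same sign in pair 1, whose arrays share a slide, in 63.5% of 1251 calls, which left a part played by slide open. A random draw of features would give 51.0%. With pairs 2, 3 and 4 left out in turn the share was 83.6%, 68.7% and 70%, where a random draw would give 51.1%, 52.6% and 46.3%. Features on an array are not independent, so these figures are not chance levels for the calls and the differences are not a test. Of the 8 splits that part all 4 pairs, 1 gave as many genes, the real one, with 649 as the highest of the others, and 8 splits are too few for a share under 0.05. With normexp and the block together the count was 18, 10 higher and 8 lower, and the cause of that difference was not tested.

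The lenient count was at least as large as the real 382 in 14 of the 35 splits, with 4170 as the highest of the others, so chance cannot be excluded over all splits. Splits that keep pairs together carry what the numbers share, and in the other splits that part all 4 pairs the count was 33 to 142, with 8 splits too few for a share under 0.05. A real count of 0 is reached by any split, so the 35 of 35 splits with as many genes past the adjusted threshold, and the 35 of 35 with as many gene lists, say nothing about chance. The highest of the other splits were 2951 genes and 4 lists. The 2951 came from parting replicates 1 and 3 from 2 and 4, which points to a structure of the samples other than the groups.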

How the results depend on the processing

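The tests that left out replicates 1 and 3 or joined 2 choices, including an estimated correlation with another setting, were chosen after seeing the data. The count of genes past the adjusted threshold stayed at 0 under every alternative, and 27 of 49 named genes and 1 of 14 lists, immediate early genes, kept their direction. The 27 include the genes named for having no overlap between groups. For the same probe, their direction cannot reverse when 1 array is left out. Not every gene was measured under every alternative. Within both slides 1 and 2, 32 of the 49 kept their sign, and immediate early genes had a mean of -0.12 within slide 2. Each of these slides held 1 normoxia array. The lenient count of 382 became 23 with normexp, 137 with median scaling, 1120 with array weights, 1112 with the replicate block, 192 with slide as a block, 215 at a fold of 2, 924 without replicates 1 and 3 of both groups, 820, 1116 and 18 with the replicate block joined to the all-array filter, quantile normalization and normexp, and 177 to 594 with 1 array left out. From 0, the lists passing became 1 with the mean of probes, 2 each with array weights, slide as a block and without replicates 1 and 3, and 0 to 2 with 1 array left out, but 0 in each of these settings at an estimated correlation. Without replicates 1 and 3 they were glycolysis (0.66) and ribosomal proteins (-0.35). Beyond the lenient count and the counts adjusted over the list alone for matrix, ATP synthase and nerve genes, the replicate block changed no other call. The separation became 0.00313 over the 1000 most variable genes, and -0.0204 to 0.00419 with 1 array left out. Only 59.6% of probes were well above background on normoxia 4, and the number of arrays limits the precision. The cause of each change below was not tested.

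Values (log2) that changed sign were, with normexp, HK1 -0.54, VEGFA -0.33, GUCY1B1 -0.16, AGTR1 0.11, COL1A1 -0.14, TYMS -0.0980, MX2 -0.13, FOS -0.28, AHSP -0.70, GFAP -0.47, MB -0.56, HIF1A -0.66, EPAS1 -0.63, glycolysis -0.19, hypoxia-inducible factor targets -0.36, extracellular matrix -0.0632, growth factors -0.19, heat shock -0.12 and endothelial markers -0.30, and the replicate block with normexp gave the same values. With normexp the median of all features was -0.31, but features did not all move by the same amount. With quantile normalization, alone or with the replicate block, the values that changed sign were TYMS -0.24 and AHSP -0.0502. With median scaling, which moved every feature by the same -0.18 so that a change of sign restates that shift, they were TYMS -0.14, AHSP -0.0124, EPAS1 -0.17, glycolysis -0.0318, growth factors -0.0147 and heat shock -0.12. With cyclic loess they were TYMS -0.15, AHSP -0.0383, EPAS1 -0.16 and ribosomal proteins 0.12. With array weights they were EPAS1 -0.38 and heat shock -0.0654. With slide as a block they were MYLK 0.11, AGTR1 0.72, HBB -0.19, AHSP -0.23, GFAP -0.00846, EPAS1 -0.46, glycolysis -0.00769, hypoxia-inducible factor targets -0.0216 and growth factors -0.21. Without replicates 1 and 3 they were PTGS2 0.00549 and EPAS1 -0.50. With 1 array left out, the ranges were CNN1 -1.04 to 0.14, AGTR1 -0.80 to 0.26, TYMS -0.27 to 0.42, MX1 -0.64 to 0.0602, DDIT3 -0.88 to 0.31, NOS2 -2.15 to 0.0324, AHSP -0.84 to 0.94, LEP -1.21 to 0.16, MYH1 -2.23 to 0.0923, HIF1A -0.18 to 1.51, EPAS1 -0.54 to 0.56, glycolysis -0.0259 to 0.43, hypoxia-inducible factor targets -0.14 to 0.71, vasoactive receptors -0.33 to 0.0571, growth factors -0.0340 to 0.40, ribosomal proteins -0.44 to 0.0859, inflammatory mediators -0.43 to 0.18, heat shock -0.14 to 0.31, antioxidant -0.74 to 0.0250, leukocyte markers -0.87 to 0.10, adipocyte markers -1.25 to 0.28 and skeletal muscle markers -1.0 to 0.32. Values that kept their sign but moved by over 1.5 times with 1 array left out were PFKL 0.38 to 0.93, HK1 0.48 to 1.54, VEGFA 0.39 to 1.24, MYLK -0.89 to -0.0876, GUCY1B1 0.14 to 0.78, COL1A1 0.56 to 1.40, ATP5MC2 -0.71 to -0.34, ATP5MC1 -0.68 to -0.22, PCNA -0.39 to -0.15, RPS26 -0.83 to -0.32, MX2 0.0140 to 0.80, PTGS1 -0.66 to -0.26, PTGS2 -0.47 to -0.12, JUND 0.34 to 1.14, TXN -0.43 to -0.23, TIE1 1.95 to 3.33, CD3E -1.13 to -0.13, HBB 0.0502 to 0.73, SCD -2.12 to -0.0624, GFAP 0.29 to 1.13, MB 0.26 to 0.90, SLC2A1 -0.91 to -0.0972, IGF2R 1.49 to 2.71, extracellular matrix 0.25 to 0.82, immediate early genes 0.28 to 0.64 and endothelial markers 0.40 to 1.30.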
